A study of Arabidopsis thaliana with 6 samples.

How the data were processed

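Total RNA of hypocotyl callus was extracted with TransZol Up and 1 µg per sample was made into libraries with a TruSeq RNA kit, per the labels' protocols. The labels do not state whether the kit kept strand. The authors deposited a single table of TPM (transcript abundance scaled to a fixed library total) for 31305 loci and 6 libraries. The submitters' processing notes name STAR 2.7.10a, RSEM 1.3.1 and the TAIR10 genome, without stating the role of each. TPM divides by transcript length and by each library's total, so a few very abundant transcripts lower the values of all others, and sequencing depth cannot be recovered from it. Where near-identical genes share reads, an estimated abundance can split them.

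Column names matched the sample titles, and all 6 columns were used in groups of 3. Locus codes were matched to the TAIR10.1 reference annotation: 31217 matched and 88 organelle codes did not. Coordinates, strand, symbols and product descriptions come from TAIR10.1, and the table itself holds no coordinates. Of 366 loci in the gene lists, 352 had the listed symbol in the reference, and the others are named as the reference names them.

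Genes with a mean of at least 1 TPM over the 6 libraries were kept (18629). Values were taken as log2(TPM + 1), so fold changes on this scale understate changes of low genes, and ratios printed as "times" are ratios of mean TPM. Groups were compared with limma 3.58.1 (R 4.3.3; moderated test with a mean-variance trend) with Benjamini-Hochberg adjustment over kept genes and a threshold of 0.05. Every adjusted p of a gene is limma's. RAP2.12 was also tested with an exact two-sided permutation test of its 6 values.

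Gene lists were fixed before the data were examined: ERF-VII factors, hypoxia response, callus and root stem cell regulators, shoot meristem regulators, auxin response, auxin synthesis and transport, cytokinin response, cell cycle, reactive oxygen production and scavenging, salicylic acid and defence, jasmonate, ethylene, abscisic acid and water deficit, glycolysis, sugar starvation, photosynthesis, cell wall, flavonoid, heat shock and protein folding, iron, nitrate, phosphate starvation, and markers of xylem, phloem, cambium, epidermis, root hair and root cap, endodermis and stomatal lineage. The 27 lists with at least 3 kept members were tested with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. A second set test, limma's fry, was planned beside camera, for direction and for mixed changes, in which members may move either way. Families came from 42 words, also fixed before, searched as substrings of product descriptions (so that "thionin" also finds glutathione genes), and 32 with at least 10 kept genes were tested in the same way. Called genes within 1 Mb of RAP2.12, itself left out, were compared with the rest by Fisher's exact test.

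The rule for named genes was fixed before the data were examined. It takes the ERF-VII genes; up to 12 genes each way with an adjusted p under 0.05, groups that do not overlap and at least 5 TPM in the higher group, by log2 fold change; if fewer than 6 pass in a direction, the 6 with the smallest p; up to 4 called members of each list, or the member with the smallest p; and the 2 members with the smallest p of each called family. ICS1, EDS1, ADH1, XCP1, WOX11, GH3.3, AT1G07887 and AT1G53490 fall outside it and were chosen after their values were seen.

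Called genes were searched against the genome with BLAST 2.17.0 for stretches of at least 100 bases at 95% identity or more. The limma step was tested on simulated data made from the 18629 kept genes of this comparison with 200 changed: 44% of 2-fold and 98% of 4-fold changes were recovered, and 7 of 149 calls were false. In the real data a split that mixed the genotypes called 153 genes, so this share need not hold for the real calls. For the camera step, 1 list of 18 genes was shifted by -1 (log2) in simulated data and called, with 0 of the other lists called; the simulated genes were independent, so this does not test lists whose members move together. Alternatives were other pseudocounts (0.1 and 0.5), no filter or a mean of 5 TPM, median-of-ratios and quantile scaling, removal of organelle genes, other variance priors, the replicate number as a block, each library left out in turn, other thresholds, windows of 5 Mb and 250 kb, and an estimated correlation for lists. Added after the data were seen were rescaling to nuclear protein-coding genes, leaving out both replicates 1, an estimated correlation for families, and a block that follows the number of detected genes.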

Results

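Messenger RNA was measured by bulk RNA sequencing in callus, the unorganised tissue that plant explants form on medium rich in auxin and cytokinin. Hypocotyl pieces of 1-week-old Arabidopsis thaliana seedlings had spent 7 days on callus-inducing medium. There were 3 libraries of the wild type Col-0 and 3 labelled rap2.12-2, named after RAP2.12, a group VII ethylene response factor (ERF-VII) whose protein is degraded when oxygen is present and activates genes for low oxygen. The series describes the replicates of each genotype as biological. The comparison asks which transcripts differ between the genotypes in callus. Each library is given as TPM for 31305 loci, a unit that keeps no sequencing depth, so the depth behind each value is unknown and precision is judged from the spread between libraries. Col-0 replicate 1 stood apart: its listed values summed to 845341 TPM, 15.5% short of the full TPM total, against 984523 to 992724 in the other 5 libraries, and its organelle-encoded genes summed to 12005 TPM against 157 to 537. A single organelle locus, ATMG01390, made up 7846 of these 12005 TPM, against 78.7 to 190 TPM in the other libraries. Nuclear ribosomal RNA genes were also highest in Col-0 replicate 1, at 31123 TPM against 11949 to 24551. The library labelled rap2.12-2 replicate 1 lay furthest along the first principal component (-69.2, on an axis holding 44.3% of the variance). Pearson correlations between libraries, across genes, ran from 0.917 to 0.978.

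RAP2.12 transcript was higher, not lower, in the libraries labelled rap2.12-2. RAP2.12 (AT1G53910, chromosome 1, 20134844 to 20137013, plus strand, TAIR10.1) measured 123, 140 and 161 TPM in Col-0 and 360, 363 and 465 TPM in the libraries labelled rap2.12-2. The means were 141 ± 19.1 and 396 ± 59.7 TPM (SD, n = 3 each), a ratio of 2.80, and the log2 fold change was 1.48 (SE 0.17, limma adjusted p = 0.026). An exact two-sided permutation test of the 6 values gave p = 0.10, the smallest that 3 against 3 allows. The label alone gives no direction for a loss of RAP2.12 function, so every direction below is that of the libraries labelled rap2.12-2 relative to Col-0. The other ERF-VII genes did not pass the test: log2 fold changes were -0.00 for RAP2.2 (AT3G14230), 0.00 for RAP2.3 (AT3G16770), 0.01 for HRE2 (AT2G47520) and -0.65 for HRE1 (AT1G72360, limma adjusted p = 0.67). In the list of 5 ERF-VII genes, RAP2.12 was the 1 gene past the threshold over all genes, and 1 gene also passed adjusted over the list alone (camera adjusted p = 0.61). The RAP2.12 call was lost on leaving out Col-0 replicate 1 (limma adjusted p = 0.17), Col-0 replicate 2 (0.053), Col-0 replicate 3 (0.22), or the libraries labelled rap2.12-2 replicate 2 (0.080) or replicate 3 (0.068), while the log2 fold change stayed between 1.36 and 1.58. The first part of RAP2.12 is identical to part of AT1G53887. It spans 399 bases, from 20134897 to 20135295, and includes 345 bases upstream of the annotated coding start of RAP2.12. AT1G53887 is annotated on the minus strand, and the strand used in counting is not given. Unless strand was used, reads from there cannot be assigned to either gene.

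**Figure D1:**
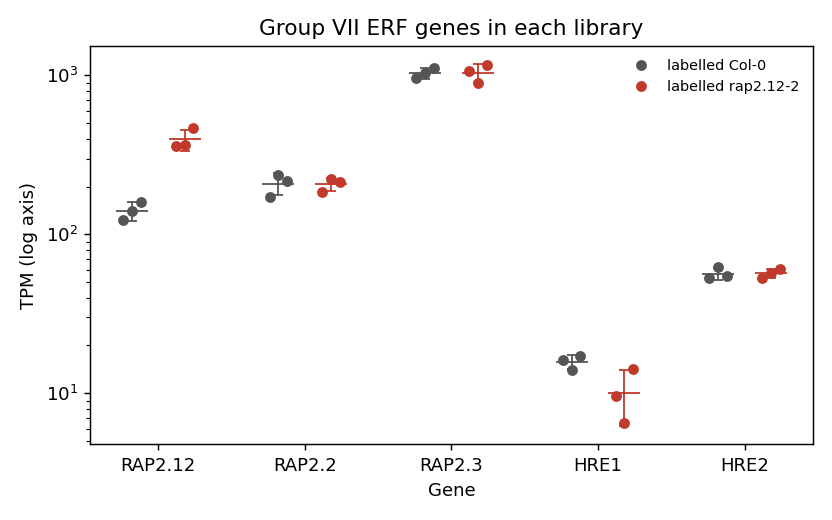
TPM on a log axis of the 5 group VII ERF genes in each library (points, n = 3 per group), with the mean (horizontal line) and SD (bar). RAP2.12 lies at 360 to 465 TPM in the libraries labelled rap2.12-2 and at 123 to 161 TPM in Col-0, while the groups overlap for RAP2.2, RAP2.3, HRE1 and HRE2.

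Among the called genes other than RAP2.12, the largest rise was in MRD1 (AT1G53480), from 4.75 ± 1.91 to 130 ± 24.8 TPM (n = 3 each), a ratio of 27.3. AT3G52870, which encodes an IQ calmodulin-binding motif protein, rose from 17.9 ± 2.87 to 143 ± 33.5 TPM (8.02 times), and AT1G52070, a mannose-binding lectin gene, from 170 ± 63.4 to 968 ± 235 TPM (5.68 times). RABG3A (AT4G09720), which encodes a RAB GTPase, rose 2.40 times, to 133 ± 7.13 TPM. The largest fall among called genes was in AT1G67105, annotated as a non-coding RNA, from 1715 ± 110 to 61.1 ± 14.6 TPM, 28.1 times lower. AT3G50840, a gene of the phototropic-responsive NPH3 family, fell from 31.4 ± 3.31 to 2.07 ± 0.447 TPM, 15.2 times lower.

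In all, 8 genes were higher and 5 lower at a limma adjusted p under 0.05 among 18629 genes with a mean of at least 1 TPM, and the 2 groups did not overlap in any of these 13. Of all kept genes, 12.7% had groups that did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 599 higher and 675 lower, 6.84% of kept genes. The remaining higher genes were AT1G53887 (3.45 times), U2.11 (AT1G04733, 5.32 times), a U2 small nuclear RNA gene, and AT4G06810 (7.11 times, 12.9 ± 2.65 TPM). The remaining lower genes were AT4G30993 (3.62 times lower), a metallo-phosphoesterase gene, AT1G13030 (3.17 times lower) and UGT73B3 (AT4G34131, 2.43 times lower), a glucosyltransferase gene. AT2G05995, a non-coding RNA gene next in order of p among the lower genes, was listed at 2.86 to 5.60 TPM in Col-0 and at 0 in the libraries labelled rap2.12-2 (limma adjusted p = 0.051). U2.11 has 11 near-identical stretches elsewhere in the genome, so its reads can be split among copies. MRD1 lies on the minus strand and overlaps AT1G07887 (log2 fold change 2.09) and AT1G53490 (0.66) on the plus strand. The strand used in counting is not given. Unless strand was used, reads from the overlapping parts cannot be assigned to 1 of these genes. The counts leaned on single libraries: 19 higher and 2 lower without Col-0 replicate 2, 3 and 3 without Col-0 replicate 1, 2 and 2 without Col-0 replicate 3, 3 and 3 without the library labelled rap2.12-2 replicate 2, and 5 and 6 without replicate 3 of that label. AT1G67105, MRD1, AT3G50840 and AT3G52870 passed in all 6 fits that left out a single library. Without both replicates 1, limma called 0 genes from 4 libraries, with 512 higher and 703 lower at an unadjusted p under 0.05. Median-of-ratios scaling gave 3 higher and 6 lower, and removal of organelle genes gave 6 and 6.

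Genes linked to RAP2.12 were compared with the rest of the genome, since DNA near an altered allele can carry differences of its own. MRD1, AT1G52070 and AT1G53887 all lie within 1 Mb of RAP2.12. These were 3 called genes of 358 kept there, against 9 of 18243 elsewhere (odds ratio 17.1, 95% interval 2.97 to 68.9, two-sided Fisher's exact test p = 0.0014). AT1G53887 shares part of its sequence with RAP2.12. Without it the counts were 2 of 357 (odds ratio 11.4, 1.2 to 55.4, Fisher's exact test p = 0.018). At an unadjusted p under 0.05 the excess was not found, with 28 of 357 genes near and 1244 of 18243 elsewhere (odds ratio 1.16, 0.758 to 1.72, Fisher's exact test p = 0.46), whereas an unadjusted p under 0.001 gave 5 and 61 (4.23, 1.32 to 10.5, p = 0.0087). These last 3 tests were chosen after the data were seen. The 5 near genes under 0.001 were MRD1, AT1G52910 and the neighbouring lectin genes AT1G52050, AT1G52060 and AT1G52070. Fisher's test counts such neighbours as independent genes, so this excess rests in part on a single cluster. Within 50 kb of RAP2.12, leaving out AT1G53887 and counting genes with identical values once, 12 of 18 kept genes had a positive log2 fold change (66.7%, median 0.09), against 46.7% of all kept genes, a difference that was not tested and was looked at after the data were seen. Windows of 250 kb (2 of 105, odds ratio 35.8, 3.77 to 171, Fisher's exact test p = 0.0020) and 5 Mb (4 of 1311, 6.61, 1.45 to 24.7, p = 0.0077) also held an excess. Both counts include AT1G53887, so they are not separate evidence. The 250 kb window held it and MRD1, and the 5 Mb window added only AT1G67105 to the 3 genes within 1 Mb. Some settings that called fewer genes in all still passed the test. A pseudocount of 0.1, removal of organelle genes and rescaling to nuclear protein-coding genes each kept 3 genes called within 1 Mb. Leaving out the library labelled rap2.12-2 replicate 1 or 3 kept 2. Without both replicates 1, 0 genes were called, so the test could not decide. In others a single gene was called within 1 Mb and the test no longer passed. The odds ratio there was still at least 7.28, with wide intervals. It was 9.88 with no filter (0.208 to 88.3, Fisher's exact test p = 0.11), 7.28 with median-of-ratios scaling (0.161 to 57.0, p = 0.14) and 12.8 with no variance trend (0.259 to 129, p = 0.093). Without Col-0 replicate 1, or without the library labelled rap2.12-2 replicate 2, it was 10.2 (0.215 to 91.6, Fisher's exact test p = 0.11), and without Col-0 replicate 3 the counts were 1 of 358 near and 3 of 18243 elsewhere (interval 0.324 to 213, p = 0.075). Without Col-0 replicate 2, 5 were called (odds ratio 16.1, 4.59 to 46.4, Fisher's exact test p = 4.1e-05). With a block for the number of detected genes, chosen after the data were seen, 18 of 358 genes were called near and 833 of 18243 elsewhere (odds ratio 1.11, 0.645 to 1.79, Fisher's exact test p = 0.61), so there was no excess among that larger number of calls.

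**Figure D2:**
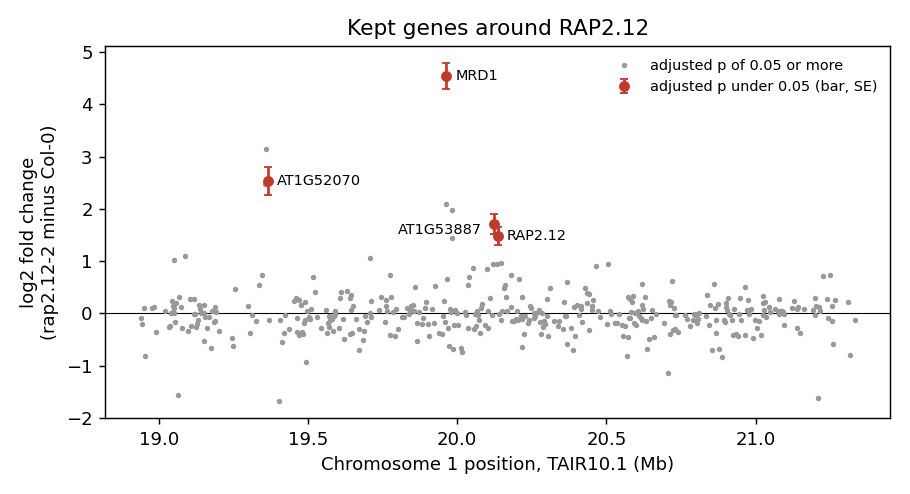
Log2 fold change (libraries labelled rap2.12-2 minus Col-0, n = 3 each) of kept genes along chromosome 1 around RAP2.12, position in Mb of TAIR10.1. Red points with SE bars are genes at a limma adjusted p under 0.05: MRD1 at 4.54, AT1G52070 at 2.54, AT1G53887 at 1.70 and RAP2.12 at 1.48.

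Genes of salicylic acid synthesis and defence lay lower as a set in the libraries labelled rap2.12-2. All 18 kept members had a negative log2 fold change, with a median of -1.50. ICS1 (AT1G74710), which encodes the isochorismate synthase of salicylic acid synthesis, measured 64.6 TPM in Col-0 and 20.2 TPM in the libraries labelled rap2.12-2. EDS1 (AT3G48090), a regulator of immunity, measured 98.0 and 45.6 TPM, and the camalexin synthesis gene CYP71A13 (AT2G30770) 5.49 ± 3.63 and 0.853 ± 0.615 TPM (n = 3 each). No member passed over all genes (CYP71A13 had the smallest p, limma adjusted p = 0.36), 13 were lower at an unadjusted p under 0.05, and 13 were lower adjusted over the list alone. The camera adjusted p was 2.4e-13 with a preset correlation of 0.01, but a split of the libraries that mixed the genotypes gave an unadjusted camera p of 2.1e-14, close to the 8.7e-15 of the real one. With an estimated correlation (0.74 between members) the camera adjusted p = 0.98, so the call was lost. The list did not pass in fry either (adjusted p = 0.79). The mean list score was 0.41, 1.56 and 0.16 in Col-0 and -1.65, -0.39 and -0.09 in the libraries labelled rap2.12-2, and an exact two-sided permutation test gave p = 0.10, the smallest possible. The lowest score was that of the library that stood furthest on the first principal component. The highest was that of Col-0 replicate 2, furthest the other way on that axis (44.8). The list median was -0.99 without the library of the lowest score and -0.99 without Col-0 replicate 2. Leaving out 1 of these 2 libraries keeps the other.

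**Figure D3:**
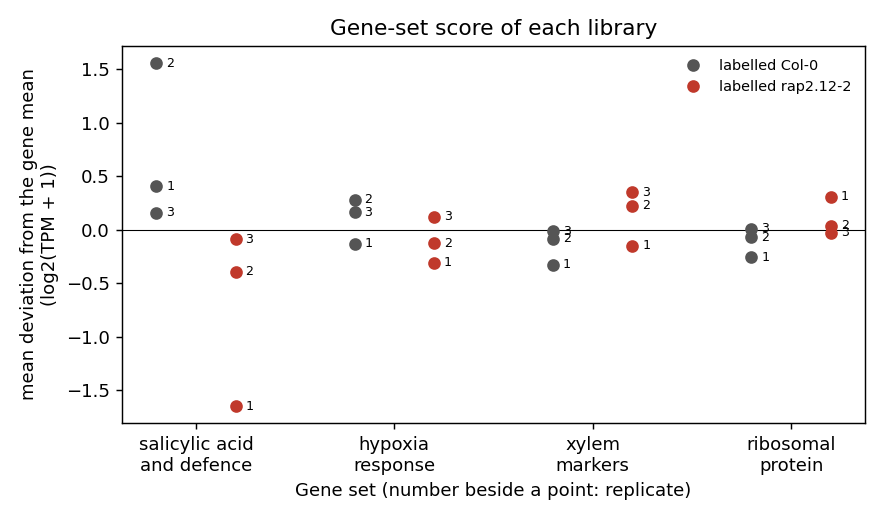
Score of 4 gene sets in each library: the mean over kept members of log2(TPM + 1) minus the gene's mean over the 6 libraries (n = 3 per group; numbers name the replicate). The groups part for salicylic acid and defence, where Col-0 lies at 0.16 to 1.56 and the libraries labelled rap2.12-2 at -1.65 to -0.09, and they overlap for the other 3 sets.

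Genes of the hypoxia response, the best known targets of ERF-VII factors, had small negative changes. Of 28 kept members, 22 had a negative log2 fold change and the median was -0.21. PDC2 (AT5G54960), a pyruvate decarboxylase gene of fermentation, measured 51.5 ± 4.43 and 33.5 ± 7.64 TPM (n = 3 each, limma adjusted p = 0.47), and the alcohol dehydrogenase gene ADH1 (AT1G77120) 1085 and 759 TPM. No member passed in limma over all genes, 4 were lower and 0 higher at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The camera adjusted p was 0.012, and the camera adjusted p = 0.98 with an estimated correlation. The camera call was also lost without Col-0 replicate 2 (adjusted p = 0.087), Col-0 replicate 3 (0.061) or the library labelled rap2.12-2 replicate 2 (0.26), and the median was -0.08 without replicate 1 of that label.

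Xylem markers lay slightly higher as a set: 8 of 9 kept members had a positive log2 fold change, with a median of 0.37. The vessel protease genes XCP2 (AT1G20850, 62.1 ± 7.57 and 91.5 ± 4.96 TPM, n = 3 each) and XCP1 (AT4G35350, 94.3 and 133 TPM) were higher adjusted over the list alone, 2 of 9, and no member passed in limma over all genes, with 2 higher at an unadjusted p under 0.05. The camera adjusted p was 0.011, and the camera adjusted p = 0.98 with an estimated correlation. The groups overlapped in the list score, with Col-0 replicate 3 at -0.01 and the library labelled rap2.12-2 replicate 1 at -0.15. Without the library labelled rap2.12-2 replicate 3 the camera adjusted p was 0.16 and the median 0.19. A block for the number of detected genes, chosen after the data were seen, also ended the call (camera adjusted p = 0.059, median 0.22), and within the 2 sets of that block the list score differed by 0.02 and 0.37.

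The other lists did not pass the camera test, but single members stood out when adjusted over the list alone. Some alternatives added camera calls: auxin response genes were lower with quantile scaling (adjusted p = 0.036) and with the block for detected genes (0.018), and without Col-0 replicate 2 jasmonate genes were higher (median 0.79, camera adjusted p = 2.7e-09) and cambium markers lower (0.010). None of these calls held with an estimated correlation, where the camera adjusted p was 0.58 and 0.56 for auxin response and 0.98 for jasmonate and for cambium markers. Among 20 kept regulators of callus and root stem cells, WOX11 (AT3G03660), a factor of root founder cell identity, measured 186 and 102 TPM and ERF115 (AT5G07310), a regeneration factor, 70.5 ± 7.45 and 40.8 ± 7.58 TPM (n = 3 each). Both were lower adjusted over the list alone, 2 of 20, and neither passed over all genes (limma adjusted p = 0.32 and 0.31; camera adjusted p = 0.74). Among 16 auxin response genes, 11 had a negative change, and IAA29 (AT4G32280, log2 fold change -1.46) and GH3.3 (AT2G23170, -1.23), both induced by auxin, were lower adjusted over the list alone, 2 of 16 (camera adjusted p = 0.095). The cambium marker WOX4 (AT1G46480, 60.2 and 40.6 TPM) was lower adjusted over the list alone, 1 of 3 kept (camera adjusted p = 0.080). Higher adjusted over the list alone were the glutathione transferase gene GSTU25 (AT1G17180, 2.49 times), 1 of 18 kept genes of reactive oxygen production and scavenging (camera adjusted p = 0.61), the ethylene synthesis gene ACO4 (AT1G05010, 2.31 times), 1 of 13 kept ethylene genes (0.95), and NRT3.1 (AT5G50200, 1.85 times), 1 of 5 kept nitrate genes (0.74). None of these genes passed in limma over all genes.

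In the remaining lists with at least 3 kept members, no member passed in limma over all genes or adjusted over the list alone, and the gene with the smallest p is given with its log2 fold change. These were RAP2.6L (-0.39) of 9 kept shoot meristem regulators (camera adjusted p = 0.97), YUC9 (0.70) of 7 genes of auxin synthesis and transport (0.95), ARR6 (0.78) of 20 cytokinin response genes (0.61) and CDKB2;1 (-0.44) of 33 cell cycle genes (0.92). THI2.1 (1.76) led 15 jasmonate genes (camera adjusted p = 0.33), ABI2 (-0.68) 11 genes of abscisic acid and water deficit (0.76), PFK3 (-1.12) 11 glycolysis genes (0.95) and DIN2 (-0.87) 3 sugar starvation genes (0.74). LHCA2 (-0.51) led 17 photosynthesis genes (camera adjusted p = 0.61), EXPA14 (1.00) 12 cell wall genes (0.75), HSP18.2 (0.26) 7 genes of heat shock and protein folding (0.61), FRO2 (0.71) 5 iron genes (0.095) and PS2 (-0.89) 4 phosphate starvation genes (0.61). Among markers of other cell types, APL (0.45) led 4 phloem genes (camera adjusted p = 0.75), PDF1 (-0.83) 3 epidermis genes (0.49), RHD6 (0.48) 3 root hair and root cap genes (0.61) and GPAT5 (-0.38) 3 endodermis genes (0.95). At an unadjusted p under 0.05, limma gave 2 higher and 2 lower cytokinin response genes and 0 of the shoot meristem, photosynthesis, heat shock, phosphate, phloem, root hair and endodermis lists. Of the flavonoid genes, CHI alone was kept (log2 fold change 0.60, limma adjusted p = 0.72). Adjusted over the list alone 1 of 1 was higher, but with a single kept gene this is its unadjusted limma p of 0.046, and 0 of 4 stomatal lineage markers were kept.

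**Figure D4:**
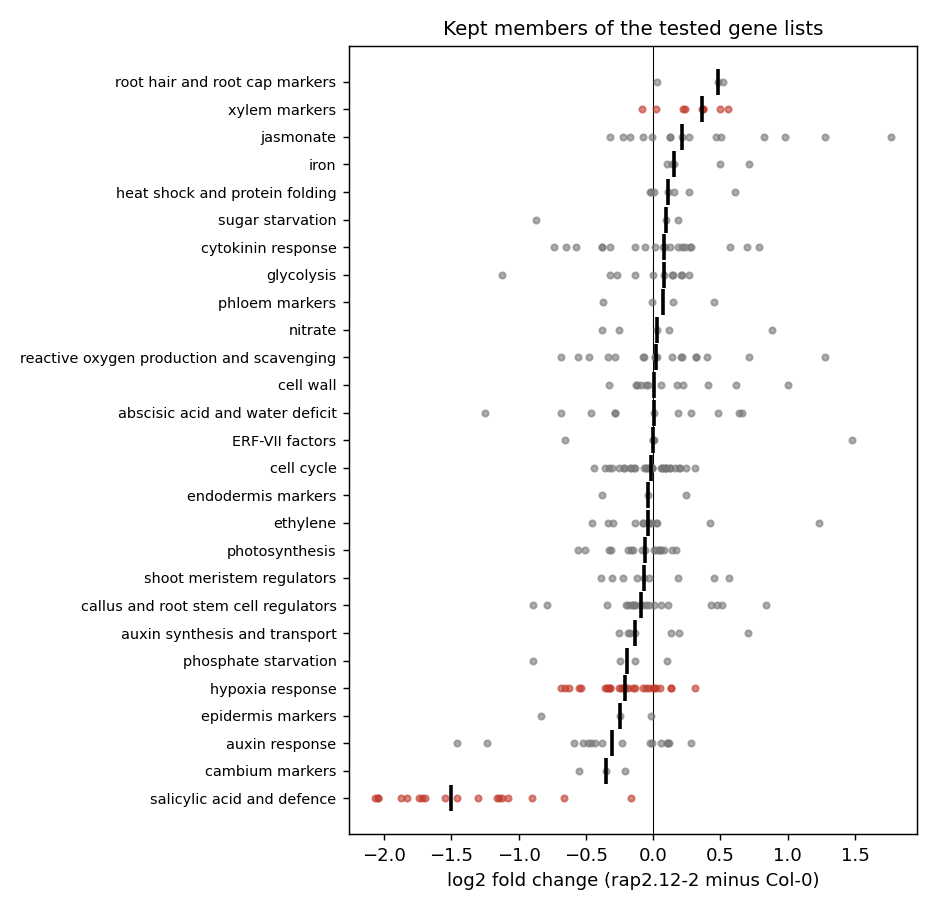
Log2 fold change (libraries labelled rap2.12-2 minus Col-0, n = 3 each) of every kept member of the 27 tested lists (points) with the list median (black bar), ordered by the median. Red marks the 3 lists with a camera adjusted p under 0.05 at a preset correlation, whose medians were -1.50 for salicylic acid and defence, -0.21 for the hypoxia response and 0.37 for xylem markers.

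Protein families showed small shifts shared by many members. Of 323 kept ribosomal protein genes, 293 had a positive log2 fold change, with a median of 0.24 (camera adjusted p = 1.2e-19, and adjusted p = 0.995 with an estimated correlation). The smallest p values in this family were those of AT2G16360 (log2 fold change -2.02) and AT3G56020 (0.76). WRKY genes, which encode transcription factors of defence and senescence, had a median of -0.22 over 49 kept genes, 37 of them negative (camera adjusted p = 0.023, and adjusted p = 0.995 with an estimated correlation), with WRKY50 (-1.56) and WRKY51 (-2.02) first by p. Kinesin genes had a median of -0.26, 24 of 27 negative (camera adjusted p = 0.016, and adjusted p = 0.995 with an estimated correlation), with ATK4 (-0.56) and AT4G26410 (0.43) first. Sugar transporter genes had a median of 0.11, 26 of 36 positive (camera adjusted p = 0.023, and adjusted p = 0.995 with an estimated correlation), with AT5G42420 (0.61) and GONST2 (0.59) first, both described as nucleotide sugar transporters. SAUR genes, named for their induction by auxin, had a median of 0.08, 17 of 25 positive (camera adjusted p = 0.027, and adjusted p = 0.995 with an estimated correlation), with SAUR9 (0.85) and AT4G31320 (0.67) first. No gene of these 5 families passed in limma over all genes. The ribosomal median was 0.13 without the library labelled rap2.12-2 replicate 1, 0.16 without Col-0 replicate 1, 0.04 without both replicates 1, 0.13 with quantile scaling and 0.15 on rescaling to nuclear protein-coding genes. Without the library labelled rap2.12-2 replicate 1 the camera adjusted p was 0.52 for WRKY, 0.76 for kinesin and 0.76 for SAUR genes. The camera call was also lost for WRKY genes without Col-0 replicate 1 (adjusted p = 0.060) or 2 (0.31) with organelle genes removed (0.14) and on rescaling to nuclear protein-coding genes (0.12), for kinesin genes without Col-0 replicate 1 (0.060) or 3 (0.067), for sugar transporter genes without Col-0 replicate 2 (0.15) or the library labelled rap2.12-2 replicate 2 (0.090), and for SAUR genes at a mean of at least 5 TPM (0.077). Without both replicates 1 the camera adjusted p was 0.70 for WRKY, 0.70 for kinesin and 0.67 for SAUR genes.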

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

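Under the alternatives run, no called value changed sign. The salicylic acid and defence list kept its camera call in every alternative except the estimated correlation. It did not pass in fry, the second set test, for direction (adjusted p = 0.79). The hypoxia response (fry adjusted p = 0.99) and xylem markers (0.79) did not pass in fry either. For mixed changes fry passed for the ERF-VII list (adjusted p = 0.0024), which holds RAP2.12. It also passed for the families UDP-glucosyl (0.011) and calmodulin (0.032), with 1 called gene each. Families without a called gene that passed were cytochrome P450, intrinsic protein and late embryogenesis (0.032 each) and UDP-glycosyl (0.044). The salicylic acid and defence list did not pass (0.26). The cause of the changes below was not tested, except that leaving out libraries also leaves fewer samples.

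RAP2.12 kept a log2 fold change of 1.48 but lost its limma call with no filter (adjusted p = 0.062), without the variance trend (0.077) and with the replicate block (0.062), and it was 1.45 (0.31) without both replicates 1; over all alternatives its adjusted p ran from 0.00011 to 0.31. Without a single library it ranged from 1.36 to 1.58. Genes called higher and lower numbered 3 and 3 with no filter, 2 and 3 without the trend, 3 and 6 with median-of-ratios scaling, 2 and 2 at an adjusted p under 0.01, and 0 and 0 without both replicates 1. Without a single library, 2 to 19 were higher and 2 to 6 lower. Of the 13 called genes, 5 were called with no filter, 7 with median-of-ratios scaling, 4 without the trend, 0 without both replicates 1, and 4 to 10 without a single library. Within 1 Mb of RAP2.12, 1 gene was called with no filter, with median-of-ratios scaling and without the trend, 0 without both replicates 1, and 1 to 5 without a single library. With an estimated correlation 0 lists and 0 families passed camera, and 0 of each had an unadjusted p under 0.05. Families numbered 2 without both replicates 1 and 2 to 7 without a single library.

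The replicate numbers gave no clear pairing of the samples: same-numbered libraries had deviation correlations of 0.20, 0.35 and -0.11. Both replicates 2 correlated best with each other, but not every library correlated best with its own number. With 3 libraries per group these values cannot exclude a pairing. With the replicate block, limma called 2 higher and 2 lower genes, 4 of the 13, and 1 within 1 Mb of RAP2.12 (odds ratio interval 0.324 to 213, Fisher's exact test p = 0.075).

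A block for the number of detected genes (18034 to 18328 in 3 libraries, 18517 to 18781 in 3) gave 187 higher and 665 lower genes, 18 of them within 1 Mb of RAP2.12, and ended the camera call of xylem markers (adjusted p = 0.059). Within the sets the xylem score differed by 0.02 and 0.37 and the defence score by -1.93 and -1.80, each comparing 1 library with 2. This block was tried because the same split of the libraries had already given the most calls, so its counts are too favourable; the other 8 splits as a block gave 4 to 7 calls. TPM keeps no depth, so how far depth limits low genes is unknown.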

Other observations

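Chosen only after the result was seen were the tests of lectin genes, of AT1G53887, of looser thresholds near RAP2.12, of an exchanged pair, of the list scores and of detected genes, the rescaling to nuclear protein-coding genes, and the bounds of every test. The other scalings, leaving out single libraries and the 1 Mb window were set before the data were examined.

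Lectin genes of the mannose-binding and jacalin type were looked at because AT1G52070 was called. Its neighbours AT1G52060 (16.2 and 137 TPM in Col-0 and the libraries labelled rap2.12-2, limma adjusted p = 0.059) and AT1G52050 (30.2 and 156 TPM, 0.14) lay higher without passing, while AT1G52130, in the same 1 Mb, measured 36.6 and 9.41 TPM. Farther away, JAL22 (AT2G39310) measured 141 and 273 TPM and JAL33 (AT3G16450) 395 and 653 TPM. Over the 18 kept lectin genes outside 1 Mb of RAP2.12 the median log2 fold change was 0.22, 12 were positive and none passed in limma. For a change of the whole lectin family, camera gave an unadjusted p = 0.0044 for these 18 with a preset correlation. With an estimated correlation camera gave p = 0.35, so whether the family shifted stays open. The median of 0.22 lies far below the log2 fold change of AT1G52070, 2.54 (SE 0.27). A shift of that median size shared by the family would therefore not account for the whole rise of AT1G52070.

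RAP2.12 was higher in the libraries labelled rap2.12-2. Library scaling as the whole cause is argued against by the lowest log2 fold change under 4 other scalings, 1.38, and an exchanged pair of libraries by the lowest value labelled rap2.12-2 being 2.24 times the highest labelled Col-0. AT1G53887 was itself higher (log2 fold change 1.70), which argues only against reads moved away from it to RAP2.12. The values of the 2 genes are not independent if reads of the shared stretch were not told apart by strand. A rise of AT1G53887 with part of its reads counted for RAP2.12 would raise both, so it stays open. An exchange of all labels between the groups, and transcripts from an altered RAP2.12 allele that may not encode a working protein, stay open. TPM per locus shows neither which part of the gene was read nor how the allele was altered.

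Called genes gathered around RAP2.12. Part of this may come from counting, since 399 bases of AT1G53887 are identical to RAP2.12 and both were higher. The 2 genes lie on opposite strands, so this holds only if strand was not used in counting. For MRD1 and AT1G52070, linked DNA that differs between the lines is a candidate explanation, with p = 0.018 by Fisher's exact test without AT1G53887, but the excess was not found at an unadjusted p under 0.05 (p = 0.46). Linked DNA and an effect of RAP2.12 on its neighbours cannot be told apart here, because either would follow the label and neither was measured.

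The salicylic acid and defence list lay lower. A single library as the whole cause is argued against by the highest median without a library, -0.99. This does not cover 2 libraries together. The lowest score was -1.65, in the library labelled rap2.12-2 replicate 1, and the highest 1.56, in Col-0 replicate 2. Leaving out 1 of these keeps the other. The remaining scores were 0.41 and 0.16 in Col-0 and -0.39 and -0.09 in the libraries labelled rap2.12-2. Whether libraries with fewer or more detected genes lie behind the difference cannot be decided. With these 2 sets as a block the list scores differed by -1.87 (SE 0.14, 3 residual degrees of freedom), and the same block ended the call of xylem markers. Each set compares 1 library with 2, and the single libraries were the library labelled rap2.12-2 replicate 1 and Col-0 replicate 2. These had the most extreme scores and also the fewest (18034) and most (18781) detected genes. Within a set, score and detection are therefore not separated. That block was chosen after the data were seen, so the size of the difference is not relied on. A state of single cultures that moves the whole list together cannot be told apart from an effect of genotype: members correlate at 0.74, so the list is close to a single measurement per library, and the exact permutation p = 0.10 is the smallest possible.

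Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 13 genes and the highest other 153, and 2 of the 10 gave at least as many. That other split, Col-0 replicates 1 and 3 with the library labelled rap2.12-2 replicate 1 against the rest, points to a structure of the samples that does not follow genotype. The real split called 3 lists and the highest other 5, with 5 splits giving at least as many. For salicylic acid and defence the unadjusted camera p at a preset correlation was 8.7e-15 in the real split, but 2.1e-14 with Col-0 replicates 1 and 2 and the library labelled rap2.12-2 replicate 3 against the rest, and 1.8e-09 with replicate 2 of that label in its place. The real split called 5 families and the highest other 13, and all 10 splits gave at least 5.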
